A study of Mus musculus with 6 samples.

How the data were processed

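Total RNA of liver non-parenchymal cells from 6 male mice, 3 wild type and 3 SRA-/-, was made into libraries with a KAPA total RNA kit and depletion of ribosomal RNA, per the labels' protocols. The titles call the replicates biological. Groups and replicate numbers were taken from the titles. Per the submitters' processing notes, FastQC, STAR and featureCounts were used with genome build mm39. Per the file headers, the authors counted reads over exons by gene name with featureCounts 2.0.2 on GENCODE vM26, with paired-end input and without strand. The deposited values are these raw counts, 1 file per library, not normalized and not pooled. Trimming and the aligner's version are not given in the sources used here. The header's command does not ask for read pairs, so each mate was counted, and the values bear the mark of this: 68.5% to 71.9% of counts from 1 to 4 were even, against 53.6% to 55.6% of counts from 21 to 100. A fragment thus mostly counts as a pair, and counting error is larger than the counts alone give. Reads aligned to several places or to several genes were not counted under the command's settings, which lowers genes with near-identical copies. Genes were summed by name, so different loci that share a name share a value. Coordinates are those of the count files in mm39.

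Counts were analysed in R 4.3.3 with edgeR 4.0.16. Of 53546 genes, 20541 passed filterByExpr, and TMM factors ran from 0.896 to 1.08. A quasi-likelihood model (glmQLFit, robust, with glmQLFTest) on group alone gave log2 fold changes, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The standard error of a log2 fold change was taken from the fold change and its F statistic. The common biological coefficient of variation was 0.282. With 3 against 3 libraries no exact permutation test of a single value can give a p below 0.1, so p-values come from models fitted across genes. Of the tested genes 661 (3.22%) had an unadjusted p under 0.05, 477 higher and 184 lower in SRA-/- libraries, and 1499 (7.30%) did not overlap between the groups, where chance gives 10%.

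For depth, the totals of 23757203 to 44003902 counts give floors of 0.136 to 0.253 CPM per library. Floors were taken as 6 counts, which stand for 3 fragments with both mates counted, and folds against a group with 0 counts use 6 counts over the group. Where a group held 1 to 6 counts, the ratio of pooled CPM is given with an exact Clopper-Pearson interval at 95%, computed on counts divided by 2. Floors cover counting error only. The procedure was tested on simulated data drawn from these libraries' means and sizes, in which 19930 of 20541 genes passed the filter and were tested. All changed genes were among them. Of 67 genes changed 1.5-fold 0 were called, of 67 changed 2-fold 6 (8.96%), of 66 changed 4-fold 58 (87.9%) and of 19700 tested unchanged genes 6 (0.0305%). Both lists moved 1.5-fold were called, and 0 of 30 unchanged lists. Genes were drawn independently there, so the simulation does not test how correlation between genes of a list bears on camera with a preset correlation.

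Before the data were examined, 39 gene lists for pathways and cell types, the tests, the named genes and most alternatives were fixed. Lists with at least 5 tested genes were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and members were also adjusted over the list alone. Names in 3 cases were matched through RefSeq synonyms and 1 symbol was not matched. The rule named Msr1, then per direction the 10 genes with the largest change among those past the threshold, with a mean of at least 1 CPM, no overlap between the groups and a symbol that is not a predicted gene or clone. With 4 such genes higher and 0 lower, the rule took the 10 with the smallest p per direction that met the other criteria. It also named up to 3 members of each list by p, the most abundant member of each cell type list, and called genes within 10 Mb of Msr1. Some list members that the rule named are not reported here.

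Alternatives were DESeq2 size factors, library totals alone, DESeq2 1.42.0, limma-voom with quality weights, no filter on low counts, a filter of 1 CPM in 3 libraries, removal of mitochondrial and hepatocyte genes, a 1.5-fold threshold, the replicate number as a block, each library left out in turn, an estimated inter-gene correlation, fry, and windows of 5 and 20 Mb and the whole chromosome around Msr1. Chosen after seeing the data were the mean of the hepatocyte list as a covariate and the removal of wild type replicate 1, lowest in most immune lists, together with SRA-/- replicate 2, the SRA-/- library with pancreatic transcripts. That pair was picked on measured expression, so its results describe how far these 2 libraries carry the counts and are no independent test. A list of 21 genes of pancreatic acinar cells was also chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.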

Results

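RNA was sequenced from liver non-parenchymal cells, the fraction that holds endothelial cells, stellate cells, Kupffer cells and other leukocytes, of male mice given acetaminophen at 400 mg/kg into the peritoneum. The cells were taken 6 h after the injection. Acetaminophen at such doses injures hepatocytes through a reactive metabolite. There were 3 libraries from wild type mice and 3 from SRA-/- mice, which lack scavenger receptor A, a receptor of macrophages for modified lipoproteins and other polyanionic ligands that is encoded by Msr1. The series carries 1 comparison, SRA-/- against wild type after the same injection, with wild type as the reference, on the question of how the receptor bears on hepatic inflammation after acetaminophen. Untreated mice were not analysed here, so no value is a response to acetaminophen. Gene counts per library summed to 32520128, 25061773 and 31172636 for wild type replicates 1, 2 and 3 and to 44003902, 29757016 and 23757203 for SRA-/- replicates 1, 2 and 3. At these depths 6 counts, which stand for 3 fragments with both mates counted, correspond to 0.136 to 0.253 CPM, the usual unit of counts scaled to library size.

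Hepatocyte RNA was present in every library. Genes of a hepatocyte list took 5.06% to 13.9% of the counts, and albumin (Alb) alone took 1.76% in wild type replicate 3 and 6.31% in SRA-/- replicate 3. Genes of the mitochondrial genome took 6.64% of the counts in SRA-/- replicate 3 and 21.1% in SRA-/- replicate 2. Log2 CPM of pairs of libraries correlated across genes with r between 0.947 and 0.977, and genes are not independent replicates. Wild type replicate 3 was lowest and SRA-/- replicate 3 highest in the hepatocyte list. Transcripts of 21 genes of pancreatic acinar cells, a list chosen after the values were seen, summed to 17298, 13954 and 34425 counts in wild type replicates 1, 2 and 3 and to 237, 11283 and 76 in SRA-/- replicates 1, 2 and 3. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 31.8.

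Msr1, the targeted gene (chromosome 8, 40034726 to 40095714, mm39), still gave reads in every SRA-/- library. Its counts were 1123, 1936 and 3838 in the wild type libraries and 1848, 1005 and 925 in the SRA-/- libraries, which is 75.2 ± 37.6 CPM (SD, n = 3) against 38.6 ± 4.44 CPM (SD, n = 3). The log2 fold change was -0.96 ± 0.33 (SE), with an adjusted p of 0.9999 by edgeR's quasi-likelihood test, and wild type replicate 1, at 38.6 CPM, lay within the range of the SRA-/- libraries. The labels do not name the disrupted exon, and a count summed over the whole gene can hold transcripts that make no receptor, so this value neither bears out nor contradicts the genotype labels. Before adjustment over all genes, the p for Msr1 was 0.0166 by edgeR, 0.00448 by DESeq2 and 0.00149 by limma-voom with quality weights. Without wild type replicate 3 the log2 fold change was -0.54, with an unadjusted p of 0.0652 by edgeR. Without wild type replicate 1 it was -1.27, with an unadjusted p of 8.06e-05 and an adjusted p of 0.0951 by edgeR.

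**Figure D1:**
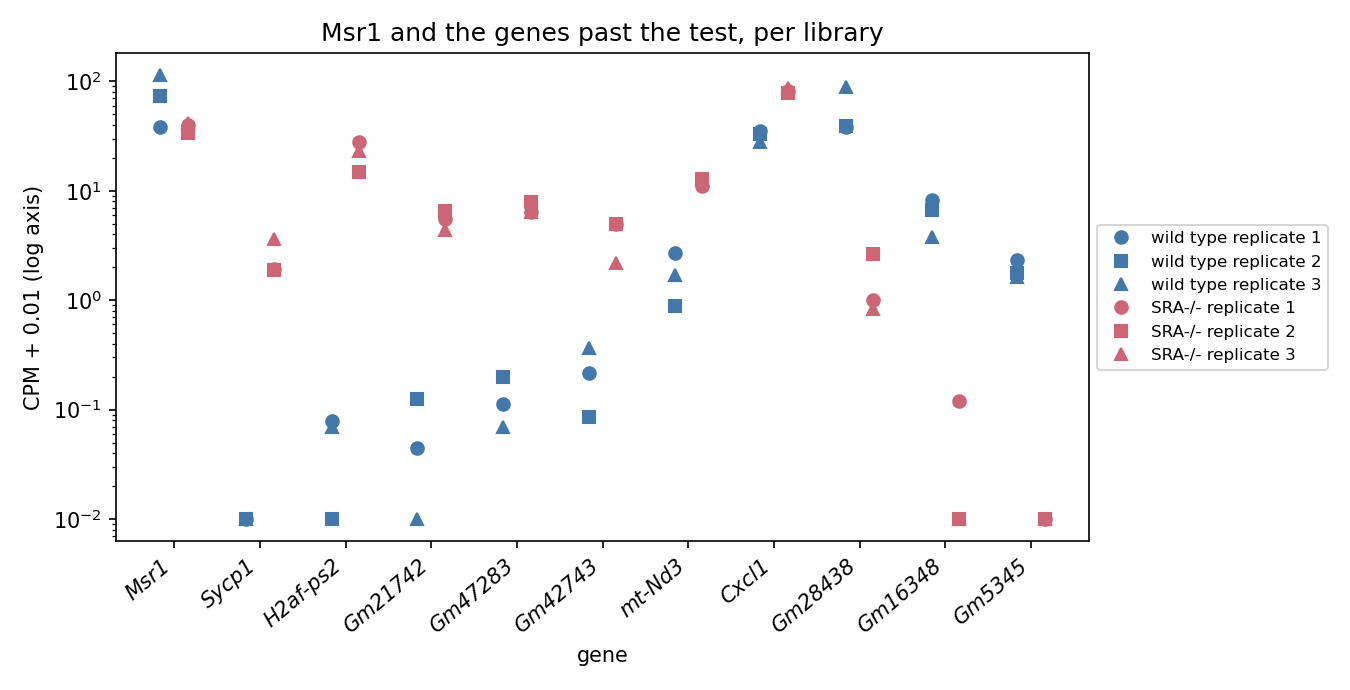
CPM plus 0.01 on a log axis for Msr1 and the 10 genes past edgeR's test, 1 point per library, wild type in blue and SRA-/- in red. Msr1 overlaps between the groups, whereas Cxcl1 lies between 27.7 and 35.0 CPM in the wild type libraries and between 78.6 and 87.6 CPM in the SRA-/- libraries.

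Cxcl1, which encodes a chemokine that attracts neutrophils (chromosome 5, 91039100 to 91040974), rose in SRA-/- cells from 32.0 ± 3.86 CPM to 82.3 ± 4.66 CPM (SD, n = 3 each), a log2 fold change of 1.36 ± 0.17 (SE) with an adjusted p of 0.0380 by edgeR. It was higher in each SRA-/- library than in each wild type library. Its adjusted p was 0.471, 0.0681, 0.281 and 0.242 without wild type replicate 2, wild type replicate 3, SRA-/- replicate 1 and SRA-/- replicate 3, with log2 fold changes between 1.27 and 1.39. Tested against a 1.5-fold change, it had an adjusted p of 0.277.

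H2af-ps2, a histone pseudogene (chromosome 13, 51356763 to 51357101), was all but absent from wild type libraries, with 2, 0 and 2 counts, and gave 1285, 447 and 505 counts in SRA-/- libraries (edgeR adjusted p 0.000290). Its ratio of pooled CPM was 510-fold, with an exact 95% interval of 141-fold to 4213-fold that covers counting error only and takes 2 counts as 1 fragment. Sycp1, a gene of the meiotic synaptonemal complex (chromosome 3, 102725815 to 102843416), had 0 counts in all 3 wild type libraries and 88, 56 and 80 in SRA-/- libraries (adjusted p 0.0297). It was at least 34.0-fold higher there, against a floor of 6 counts, or 3 fragments, over the wild type group. mt-Nd3, a subunit of complex I (mitochondrial genome, 9459 to 9806), rose from 1.76 ± 0.92 to 12.2 ± 0.96 CPM (SD, n = 3 each) with an adjusted p of 0.0474 by edgeR. Sycp1 had an adjusted p of 0.0976, 0.126 and 0.116 without wild type replicate 2, SRA-/- replicate 1 and SRA-/- replicate 3. mt-Nd3 had 0.101, 0.115, 0.281, 0.0784 and 0.276 without wild type replicate 2, wild type replicate 3 and SRA-/- replicates 1, 2 and 3. With a filter of 1 CPM in 3 libraries mt-Nd3 was not called.

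In all, 10 of 20541 tested genes changed by edgeR, 7 higher and 3 lower in SRA-/- cells. Beside Cxcl1, H2af-ps2, Sycp1 and mt-Nd3 these were 6 predicted genes. The rule named Gm5345 and Gm16348, near Msr1. The other 4 lie outside it and were chosen after their values were seen. On the Y chromosome, Gm47283 (90796007 to 90827734) and Gm21742 (90848682 to 90855309) rose, the first by a log2 fold change of 5.88 ± 0.40. Gm21742 had 1, 3 and 0 counts in wild type and 254, 196 and 96 in SRA-/- libraries, a ratio of 124-fold with an interval of 34.1-fold to 1032-fold, taken as for H2af-ps2. Gm42743 (chromosome 3, 96177037 to 96186317) rose by 4.19 ± 0.54. Gm28438 (chromosome 1, 24651856 to 24652200), which lies in a nuclear copy of mitochondrial sequence, had a log2 fold change of -5.22 ± 0.53, with 1116, 1023 and 3018 counts in wild type and 46, 79 and 18 in SRA-/- libraries. Gm16348 on chromosome 8 had 241, 177 and 126 counts in wild type and 5, 0 and 0 in SRA-/- libraries, 119-fold lower with an interval of 36.9-fold to 722-fold. Gm5345 on the same chromosome had 67, 46 and 55 counts in wild type libraries and 0 in each SRA-/- library, at least 30.7-fold lower against 6 counts over the SRA-/- group. The edgeR adjusted p was 0.000843 for Gm47283, 0.00478 for Gm21742, 0.0461 for Gm42743, 0.0109 for Gm28438 and Gm16348 and 0.0224 for Gm5345. Near-identical copies share reads and Gm42743 and Gm21742 overlap other genes, so the values of H2af-ps2, Gm28438, mt-Nd3 and the predicted genes are uncertain.

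The calls of H2af-ps2, Gm47283 and Gm21742 held whichever library was left out. Gm28438 had an adjusted p of 0.125, 0.124 and 0.0951 without wild type replicate 1, SRA-/- replicate 1 and SRA-/- replicate 3. Gm42743 had one of 0.0713, 0.219, 0.281, 0.0740 and 0.0784 without wild type replicates 1 and 2 and SRA-/- replicates 1, 2 and 3. It was also not called with library totals alone or with a filter of 1 CPM in 3 libraries. Gm5345 had an adjusted p of 0.101, 0.118 and 0.0784 without wild type replicate 2, SRA-/- replicate 1 and SRA-/- replicate 3. Gm16348 had 0.0639 and 0.0803 without wild type replicate 2 and SRA-/- replicate 3. With 1 library left out, fitted log2 fold changes ran from 6.16 without wild type replicate 3 to 8.11 without wild type replicate 2 for Gm21742. They ran from -10.46 without SRA-/- replicate 1, which leaves SRA-/- libraries at 0 counts, to -6.39 without SRA-/- replicate 2 for Gm16348. That of Gm28438 was -5.90 without SRA-/- replicate 2 and -4.69 without wild type replicate 3, and that of Gm42743 was 4.79 without wild type replicate 3. The count of changed genes was 4 (3 higher, 1 lower) without wild type replicate 2, the same without SRA-/- replicate 1, 3 (3 higher, 0 lower) without SRA-/- replicate 3 and 40 (12 higher, 28 lower) without SRA-/- replicate 2, of which 19 were of the pancreatic list. DESeq2 called 60 genes, 49 higher and 11 lower, and limma-voom with quality weights called 75, each including all 10.

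The remaining 16 genes that the rule named by direction did not pass edgeR's test. DESeq2 called 12 of them, all but Npas2, Pcm1, Fam107a and Lyve1. Limma-voom with quality weights called 11, all but Nrg1, Fcgbp, Npas2, Pcm1 and Fam107a, and edgeR with no filter on low counts called 6. Those with higher values in every SRA-/- library included Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, with log2 fold change 2.08 ± 0.33 and edgeR adjusted p 0.200. Sorl1, a sorting receptor, had 1.31 ± 0.22, Ctla4, an inhibitory receptor of T cells, 2.71 ± 0.47, Nat8 1.75 ± 0.31, Gpcpd1 0.95 ± 0.17 and the growth factor gene Nrg1 2.00 ± 0.37. Those with lower values in every SRA-/- library were led by Ctsk, the lysosomal protease cathepsin K, at -1.78 ± 0.32 with edgeR adjusted p 0.352. Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, had counts of 2396, 1859 and 1346 in wild type and 1031, 783 and 588 in SRA-/- libraries, a log2 fold change of -1.36 ± 0.26 with edgeR adjusted p 0.438. Dusp4, a phosphatase of MAP kinases, had -1.02 ± 0.20, the hormone gene Stc1 -1.72 ± 0.37, Fcgbp -2.37 ± 0.57, the clock gene Npas2 -1.25 ± 0.31, Pcm1 -0.73 ± 0.18, Fam107a -1.43 ± 0.37, Lyve1 -1.09 ± 0.29 and Klk1 -2.10 ± 0.58. Klk1 had 187, 246 and 462 counts in wild type and 46, 143 and 24 in SRA-/- libraries. Like the pancreatic list, it was highest in wild type replicate 3 and, among SRA-/- libraries, in replicate 2. Without SRA-/- replicate 2, Klk1 had an adjusted p of 0.0296 by edgeR. Ppp1r3g, Sorl1, Ctla4, Stc1, Npas2 and Klk1 overlap other annotated genes, and reads were counted without regard to strand.

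The 4 gene lists that stayed past the test whichever library was left out were those of cholesterol biosynthesis, neutrophils, B and plasma cells and MHC class II antigen presentation, all higher in SRA-/- cells by camera with a preset correlation. None of the 4 passed with an estimated correlation in place of the preset 0.01. All 24 cholesterol biosynthesis genes had log2 fold changes above 0, with a median of 0.73 (camera adjusted p 8.4e-13, and adjusted p = 0.611 with an estimated correlation). Of these, 12 had an unadjusted p under 0.05 by edgeR, 0 passed over all genes and 6 did when adjusted over the list alone, among them Lss at 0.97 ± 0.23, Sqle at 1.09 ± 0.27 and Nsdhl, whose mean went from 2.82 to 5.64 CPM, which act on the path from squalene to cholesterol. DESeq2 called 0 of the list over all genes and limma-voom 2, Lss and Nsdhl. The groups overlapped in the list's median deviation, at -0.19 in SRA-/- replicate 2 and -0.028 in wild type replicate 1. Wild type replicate 3 was lowest (-0.66) and SRA-/- replicate 3 highest (0.71), as in the hepatocyte list. Of 14 neutrophil genes 13 were above 0, with a median of 1.61 (camera adjusted p 1.49e-10, and adjusted p = 0.611 with an estimated correlation). Of these, 8 passed edgeR's test when adjusted over the list alone against 0 over all genes, 10 having an unadjusted p under 0.05. Over all genes DESeq2 called 2, S100a8 and Csf3r, and limma-voom 1, S100a8. S100a8, a calcium-binding protein abundant in neutrophils, had a log2 fold change of 1.99 ± 0.40 and G0s2 one of 1.21 ± 0.33. Mean Retnlg went from 2.29 ± 0.92 to 16.6 ± 11.7 CPM and mean Csf3r, the receptor of granulocyte colony-stimulating factor, from 10.2 ± 4.24 to 30.9 ± 12.7 CPM (SD, n = 3 each). The median neutrophil gene lay 1.26 and 1.44 log2 units above its mean over the 6 libraries in SRA-/- replicates 1 and 3, and -0.37 from it in SRA-/- replicate 2, below wild type replicate 3 at -0.11, so the groups overlapped. Wild type replicate 1 had the lowest neutrophil value, at -1.66.

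All 13 B and plasma cell genes had log2 fold changes above 0, with a median of 0.60 (camera adjusted p 1.69e-09, and adjusted p = 0.611 with an estimated correlation). Of these, 5, the same number as had an unadjusted p under 0.05, passed edgeR's test when adjusted over the list alone and 0 over all genes, where DESeq2 called 0 and limma-voom 1, Pax5. Cd79a and Pax5, genes of the B cell receptor complex and of B cell identity, had log2 fold changes of 1.13 ± 0.27 and 1.17 ± 0.31, and the most abundant member, Sdc1, which is also made by other liver cells, had 0.47 ± 0.30. Of 12 MHC class II genes 11 were above 0, with a median of 0.83 (camera adjusted p 1.92e-08, and adjusted p = 0.611 with an estimated correlation). Of these, 7, again the number with an unadjusted p under 0.05, passed edgeR's test when adjusted over the list alone and 0 over all genes. DESeq2 called 2 over all genes, H2-Eb1 and H2-Aa, as did edgeR with no filter on low counts, and limma-voom called 0. H2-Eb1 went from 34.4 ± 8.67 to 80.8 ± 24.1 CPM, H2-Aa from 41.2 ± 10.6 to 89.7 ± 25.6 CPM and H2-Ab1 from 51.6 ± 15.2 to 111 ± 30.2 CPM (SD, n = 3 each). Wild type replicate 1 also had the lowest MHC class II value, at -0.75. SRA-/- replicate 2, the lowest SRA-/- library in the neutrophil list, was the highest in both of these lists. Its MHC class II value was 0.79, against 0.32 and 0.067 in SRA-/- replicates 1 and 3. For B and plasma cell genes it was 0.81, against 0.099 and 0.27.

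**Figure D2:**
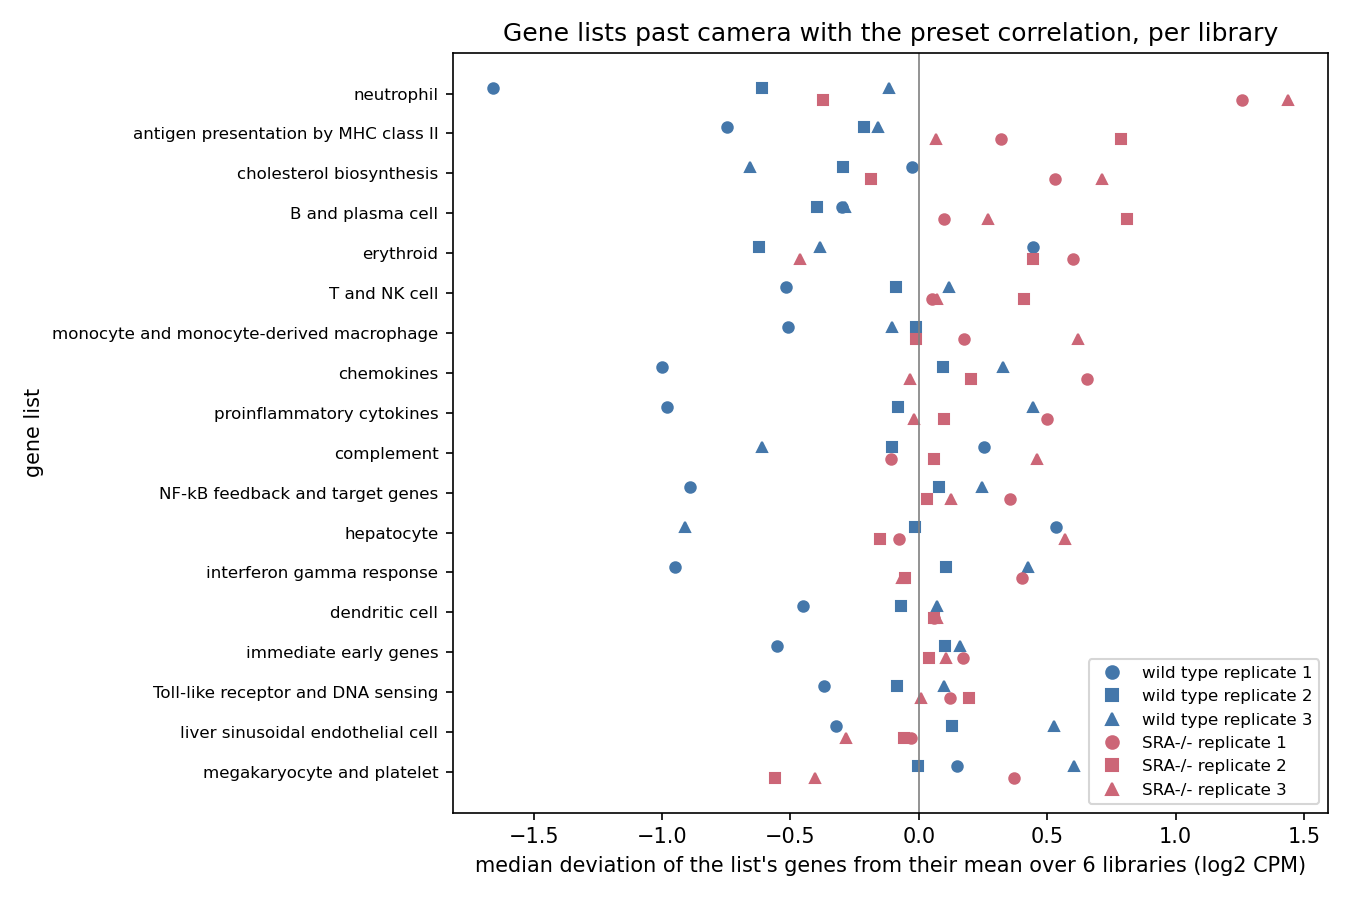
Median deviation of each list's genes from their means over the 6 libraries, in log2 CPM, for the 18 lists past camera with the preset correlation, 1 point per library, wild type in blue and SRA-/- in red. With an estimated correlation 0 of them passed. Wild type replicate 1 has the lowest value in the neutrophil list (-1.66), the cytokine list (-0.98) and the interferon gamma list (-0.95).

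In total 18 of 38 tested lists were past camera's threshold with the preset correlation, 16 higher and 2 lower in SRA-/- cells. With a correlation estimated from the data 0 were, the lowest adjusted p being 0.611 and 2 lists having an unadjusted p under 0.05, and fry, which tests whether a list's genes move on balance in 1 direction, also gave 0. Without wild type replicate 1, which had the lowest value in most immune lists, 11 lists were past the threshold with the preset correlation, 9 of them among the 18.

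Among inflammatory pathways, the chemokine list was higher (camera adjusted p 0.000228, and adjusted p = 0.611 with an estimated correlation). Of its genes 16 of 20 were above 0, and Cxcl1 was the 1 member past edgeR's test both over all genes and when adjusted over the list alone. Ccl22 had a log2 fold change of 1.15 ± 0.46 and Ccl5 0.59 ± 0.28. The list of Toll-like receptor and DNA sensing genes was higher (camera adjusted p 0.000378, and adjusted p = 0.611 with an estimated correlation). It had 23 of 26 above 0, 5 with an unadjusted p under 0.05, 0 past edgeR's test by either adjustment, and Irak3 at 0.94 ± 0.25, Tlr6 at 1.08 ± 0.33 and Tlr2 at 0.92 ± 0.33. DESeq2 and limma-voom called 0 of these over all genes. Without wild type replicate 1 the adjusted p of the chemokine and sensing lists with the preset correlation was 0.526 and 0.122.

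The list of NF-kB feedback and target genes was higher (camera adjusted p 0.000463), with 19 of 20 above 0 and Traf1 at 1.22 ± 0.36, Tnfaip2 at 0.60 ± 0.34 and Tnip1 at 0.51 ± 0.30 (adjusted p = 0.780 with an estimated correlation). Proinflammatory cytokines were higher (0.00350), with 11 of 15 above 0 and Osm at 2.17 ± 0.60, Csf1 at 0.75 ± 0.36 and Tnfsf9 at 0.56 ± 0.31 (adjusted p = 0.739 with an estimated correlation). Immediate early genes were higher (0.0138), with 16 of 21 above 0 and Nr4a1 at 0.44 ± 0.19, Egr3 at 0.40 ± 0.25 and Egr2 at 0.35 ± 0.26 (adjusted p = 0.780 with an estimated correlation). The interferon gamma response was higher (0.0244), with 18 of 22 above 0 and Ciita at 0.79 ± 0.31 and Gbp2 at 0.66 ± 0.45 (adjusted p = 0.871 with an estimated correlation). In these 4 lists 0 members passed edgeR's test over all genes and 0 when adjusted over the list alone, where the unadjusted p was under 0.05 for 1 member each. DESeq2 and limma-voom also called 0. Wild type replicate 1 was lowest in each of the 4. Camera's direction for NF-kB genes turned without it, at a median of 0.018. Without it their adjusted p with the preset correlation was 0.905, 0.850, 0.632 and 0.235, and the medians of immediate early and interferon gamma genes turned to -0.051 and -0.070. Without SRA-/- replicate 1 it was 0.0521, 0.120, 0.121 and 0.580, with an interferon gamma median of -0.058, and without SRA-/- replicate 3 it was 0.0520 for immediate early genes.

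Complement genes, most of which hepatocytes make, were higher (camera adjusted p 0.0126), with 18 of 20 above 0, 0 past edgeR's test by either adjustment or at an unadjusted p under 0.05, 0 called by DESeq2 or limma-voom, and C5ar1 at 0.73 ± 0.39, C6 at 0.41 ± 0.28 and Cfi at 0.53 ± 0.39 (adjusted p = 0.611 with an estimated correlation). Wild type replicate 3 was lowest and SRA-/- replicate 3 highest in this list, as in the hepatocyte list. The adjusted p with the preset correlation was 0.423, 0.0853 and 0.189 without wild type replicate 3, SRA-/- replicate 2 and SRA-/- replicate 3.

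Of the lists of other leukocytes, monocyte genes were higher (camera adjusted p 0.0155, and adjusted p = 0.611 with an estimated correlation), with 10 of 14 above 0 and 2 past edgeR's test when adjusted over the list alone against 0 over all genes, among them Ccr2, a receptor that draws monocytes out of the marrow, at 1.12 ± 0.31. Itgam at 0.98 ± 0.47 did not pass, and Fn1, the most abundant member, had -0.0091 ± 0.31. Dendritic cell genes were higher (0.0359, and adjusted p = 0.611 with an estimated correlation), with 9 of 14 above 0 and 1, Itgax at 1.24 ± 0.24, past edgeR's test when adjusted over the list alone against 0 over all genes, beside Ccr7 at 0.97 ± 0.30, Zbtb46 at -0.34 ± 0.17 and the most abundant member, Sirpa at 0.18 ± 0.29. T and NK cell genes were higher (0.00128, and adjusted p = 0.611 with an estimated correlation), with 15 of 20 above 0, 0 past edgeR's test by either adjustment, and Il2rb at 0.62 ± 0.21, Cd4 at 0.70 ± 0.29 and Cd3d at 0.99 ± 0.45. Each of the 3 held 2 genes with an unadjusted p under 0.05. Over all genes DESeq2 and limma-voom each called Itgax and 0 of the monocyte and T and NK cell genes. Wild type replicate 1 was lowest in all 3, and without it their adjusted p with the preset correlation was 0.235, 0.620 and 0.285. Monocyte genes had 0.0676 and 0.109 without SRA-/- replicates 1 and 3, dendritic cell genes 0.0639, 0.0863 and 0.0855 without SRA-/- replicates 1, 2 and 3, and T and NK cell genes 0.0796 without SRA-/- replicate 2. With the mean of the hepatocyte list as a covariate, an alternative chosen after seeing the data, monocyte genes had 0.0520.

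Erythroid genes were higher (camera adjusted p 0.00351, and adjusted p = 0.611 with an estimated correlation), with 9 of 10 above 0 and Slc4a1 at 0.79 ± 0.30, Hba-a2 at 0.67 ± 0.42 and Hbb-bs at 0.54 ± 0.42. Hepatocyte genes were higher (0.0340, and adjusted p = 0.871 with an estimated correlation), with 23 of 30 above 0 and Hpd at -0.29 ± 0.23, Fgg at 0.54 ± 0.46, Ambp at 0.47 ± 0.41 and Alb at 0.28 ± 0.57. Platelet genes were lower (0.000654, and adjusted p = 0.611 with an estimated correlation), with all 11 below 0 and Tubb1 at -0.71 ± 0.44, Ppbp at -0.50 ± 0.32, Gp6 at -0.64 ± 0.43 and Itgb3 at -0.31 ± 0.30. Genes of sinusoidal endothelial cells were lower (0.000654, and adjusted p = 0.780 with an estimated correlation), with all 20 below 0 and Lyve1 at -1.09 ± 0.29, Gpr182 at -0.40 ± 0.20, Flt4 at -0.48 ± 0.26 and the scavenger receptor gene Stab2 at -0.20 ± 0.27. In these 4 lists 0 members passed edgeR's test over all genes and 0 when adjusted over the list alone, and the unadjusted p was under 0.05 for 1, 0, 0 and 1. DESeq2 called 0 and limma-voom 1, Lyve1. Without wild type replicate 3 the adjusted p with the preset correlation was 0.0655, 0.128, 0.0822 and 0.533. Erythroid genes also had 0.0525, 0.111 and 0.0718 without wild type replicate 2, SRA-/- replicate 1 and SRA-/- replicate 2, hepatocyte and endothelial genes 0.699 and 0.0520 without SRA-/- replicate 3, and platelet genes 0.147 without SRA-/- replicate 2. With the hepatocyte covariate endothelial genes had 0.0637. The hepatocyte median turned to -0.093 without wild type replicate 3 and to -0.11 without SRA-/- replicate 3.

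The Kupffer cell list did not pass, with 5 of 14 genes above 0 (camera adjusted p 0.768). Its most abundant member, the lectin gene Clec4f, had a log2 fold change of -0.19 ± 0.35, beside C6 at 0.41 ± 0.28, Cdh5 at -0.19 ± 0.27 and Marco, another class A scavenger receptor, at 1.14 ± 0.78. C6 is also in the complement list and Cdh5 in the endothelial list, so neither stands for Kupffer cells alone. Marco varied widely, at 15.7, 122 and 34.2 CPM in wild type and 45.2, 184 and 150 CPM in SRA-/- libraries. The list of other scavenger receptors did not pass either, with 9 of 18 above 0 (adjusted p 0.571) and Scara3 at 0.65 ± 0.24, Cd68 at 0.45 ± 0.17 and Cd36 at -0.54 ± 0.23. The lysosome list (0.229) held 1 gene past edgeR's test when adjusted over the list alone, Ctsk, which was its 1 gene with an unadjusted p under 0.05, and 0 over all genes, beside Gla at 0.44 ± 0.25 and Ctsc at 0.29 ± 0.21. Over all genes DESeq2, limma-voom and edgeR with no filter on low counts each called Ctsk. The efferocytosis and phagocytosis list (0.229) likewise held 1, the Fc receptor gene Fcgr1 at 1.06 ± 0.24, and 0 over all genes by edgeR, DESeq2 or limma-voom, with 2 at an unadjusted p under 0.05 by edgeR, beside Elmo1 at 0.56 ± 0.20 and Cd300lb at 0.95 ± 0.45. The mitochondrially encoded list (0.951) held mt-Nd3 by both adjustments, beside mt-Nd6 at -0.24 ± 0.38 and mt-Nd4l at 0.21 ± 0.38.

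The other lists that did not pass held 0 genes past edgeR's test by either adjustment and 0 to 3 each with an unadjusted p under 0.05. Over all genes DESeq2 called 1 of their members, Il1r2, and limma-voom 0. Nuclear oxidative phosphorylation genes had a camera adjusted p of 0.0534, with 23 of 29 below 0 and Ndufa2 at -0.40 ± 0.26, Sdhd at -0.32 ± 0.21 and Uqcrh at -0.24 ± 0.17. LXR targets had 0.172, with Plin2 at 0.61 ± 0.23, Scd1 at 0.80 ± 0.58 and Srebf1 at 0.34 ± 0.29. The type I interferon response had 0.222, with Zbp1 at 0.36 ± 0.29 and Mx1 at 0.30 ± 0.32. Stellate cell genes had 0.229, with Hgf at -0.43 ± 0.21, Pdgfrb at -0.28 ± 0.24, Ecm1 at -0.31 ± 0.28 and the most abundant member, Reln at 0.15 ± 0.26. Inflammasome genes had 0.295, with Mefv at 0.84 ± 0.40, Il1b at 0.62 ± 0.44 and Nlrp1b at 0.38 ± 0.43. Autophagy genes had 0.359, with Fundc1 at -0.42 ± 0.24, Gabarapl1 at -0.33 ± 0.19 and Bnip3 at -0.26 ± 0.20. Anti-inflammatory genes had 0.477, with Il1r2 at 1.87 ± 0.53, Il10 at -0.64 ± 0.27 and Retnla at 1.53 ± 0.78. NRF2 targets had 0.481, with Slc7a11 at 1.69 ± 0.57, Gsr at -0.63 ± 0.23 and Osgin1 at 0.49 ± 0.25. Of these, Gsr lies within 10 Mb of Msr1.

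Extracellular matrix genes had a camera adjusted p of 0.481, with Mmp9 at 1.63 ± 0.45, Loxl2 at -0.69 ± 0.21 and Mmp8 at 1.74 ± 0.56. The p53 targets had 0.481, with Sesn2 at 0.24 ± 0.19, Ccng1 at -0.25 ± 0.20 and Bid at -0.22 ± 0.21. Cholangiocyte genes had 0.498, with Spp1 at 0.61 ± 0.35, Krt19 at -0.54 ± 0.33, Krt23 at 0.96 ± 0.63 and the most abundant member, Sox9 at 0.29 ± 0.40. Cell cycle genes had 0.505, with Cdc20 at -0.82 ± 0.53, E2f2 at 0.53 ± 0.36 and Rrm2 at 0.46 ± 0.33. Heat shock genes had 0.550, with Dnajb1 at 0.36 ± 0.29, Hspe1 at 0.25 ± 0.20 and Hspa1a at 0.65 ± 0.66. Hypoxia and glycolysis genes had 0.550, with Slc16a3 at 1.45 ± 0.43, Eno1 at 0.34 ± 0.17 and Gapdh at 0.33 ± 0.18. The unfolded protein response had 0.847, with Sdf2l1 at -0.36 ± 0.21, Atf4 at 0.20 ± 0.17 and Hyou1 at -0.22 ± 0.22. For the extracellular matrix, hypoxia, Kupffer cell and mitochondrially encoded lists the median lay below 0 while the mean and the test pointed up. The mast cell list, with 3 tested genes, Kit at -0.34 ± 0.26, Hdc at 0.28 ± 0.24 and Gata2 at -0.21 ± 0.29, was too short for the test.

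Of the 100 tested genes within 10 Mb of Msr1, 2 had changed by edgeR, Gm5345 at 41306865 to 41308064 and Gm16348 at 41671176 to 41673931, both lower in SRA-/- cells and 1.21 and 1.58 Mb from Msr1. Elsewhere 8 of 20440 genes had changed, so calls were more frequent near Msr1 (Fisher's exact test, two-sided, p = 0.00103). That p rests on 2 predicted genes on the same side of Msr1, which the test takes as independent. Other genes of this window that other parts of the rule named, Nrg1, Dusp4, Pcm1 and Gsr of the NRF2 list, did not pass edgeR's test. Gsr (34142551 to 34188191) had a log2 fold change of -0.63 ± 0.23 (SE). DESeq2 called Nrg1 and Dusp4, and limma-voom called Dusp4. The count near Msr1 was 0 without wild type replicate 2 or without SRA-/- replicate 3, and against the whole of chromosome 8 the same 2 calls gave a p of 0.0938 by Fisher's exact test.

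**Figure D3:**
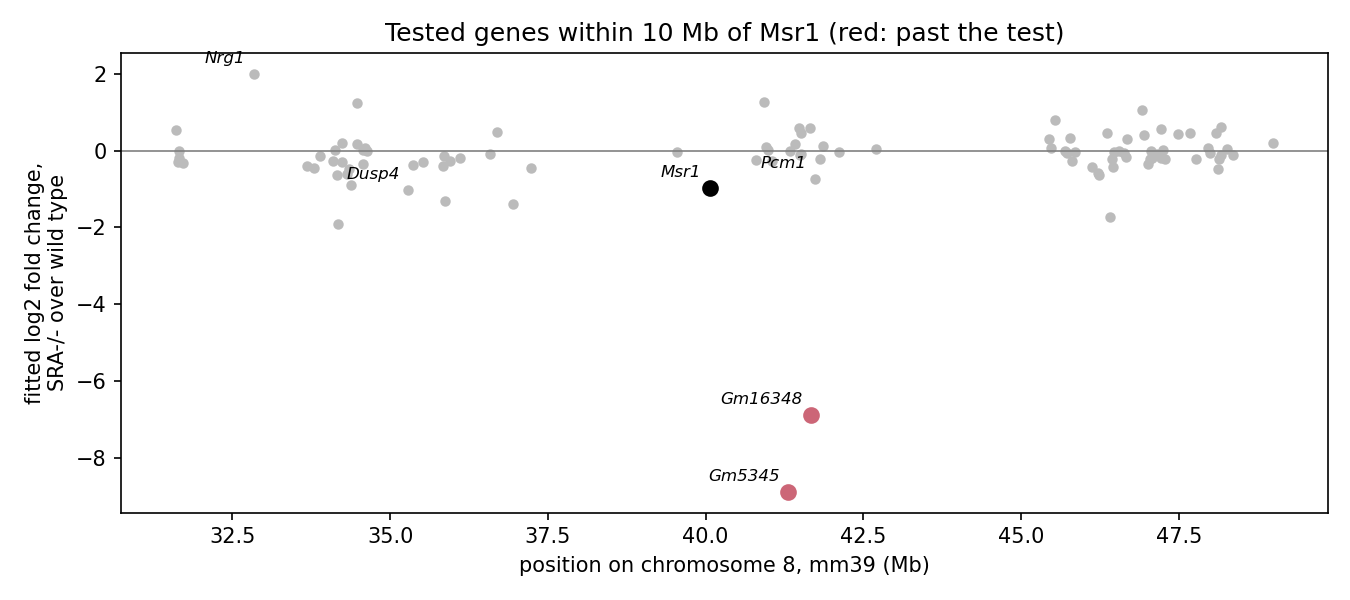
Fitted log2 fold change of SRA-/- over wild type for tested genes within 10 Mb of Msr1, against position on chromosome 8 in Mb (mm39), with the 2 genes past edgeR's test in red and Msr1 in black. Gm5345 and Gm16348 lie at -8.89 and -6.88, both fitted values and no bounds, against 0 and 5 counts over the SRA-/- group.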

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

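The hepatocyte covariate and the joint removal of wild type replicate 1 and SRA-/- replicate 2 were chosen after the results were seen, the second because of expression measured in these libraries. The count of changed genes, 10 (7 higher, 3 lower), was 60 (49 and 11) with DESeq2, 75 (64 and 11) with limma-voom and quality weights, and 32 (27 and 5) with no filter on low counts. With a 1.5-fold threshold 4 genes were higher, and Cxcl1 (adjusted p 0.277), mt-Nd3 and Gm42743 did not pass. The filter of 1 CPM in 3 libraries left 8 calls, without mt-Nd3 and Gm42743. Library totals alone left 9, without Gm42743. With the hepatocyte covariate 18 changed, 14 of them higher, and with both doubted libraries left out 101 (66 and 35), 20 of them pancreatic. DESeq2, limma-voom, the covariate and the joint removal each held all 10 genes, and the fit with no filter 9. Leaving out 1 library gave 3 to 40 changed, 3 to 12 higher and 0 to 28 lower genes; the 40 without SRA-/- replicate 2 held 19 pancreatic genes. H2af-ps2, Gm47283 and Gm21742 were called in all 17 alternatives. The number of lists called, 18, was 9 with both doubted libraries left out (7 of them shared), 0 with an estimated correlation, 0 with fry and 11 to 22 with 1 library left out. With the hepatocyte covariate it was 19, of which 15 shared; monocyte (adjusted p 0.0520), endothelial (0.0637) and hepatocyte genes (0.993) did not pass. Genes called near Msr1 numbered 0 to 3 with 1 library left out, 5 with DESeq2 and 4 with both doubted libraries left out, and the 2 calls gave a p of 0.0938 by Fisher's exact test over the whole chromosome. The log2 fold change of Msr1 ran from -1.27 to -0.54 with 1 library left out and passed the threshold in none of these fits. The cause was not tested where a value moved.

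The replicate numbers showed no sign of pairing the libraries. Deviations of same-numbered libraries correlated at -0.29, -0.14 and -0.13 across genes. No wild type library correlated best with the SRA-/- library of its own number. Larger differences between libraries, as in hepatocyte and mitochondrial share, could hide a weaker shared effect, so pairing is not excluded. With the replicate block 5 genes changed, 3 of them higher and 1 near Msr1, all 5 among the 10, and all 18 lists kept their call. Cxcl1 (adjusted p 0.337), Sycp1, mt-Nd3, Gm42743 and Gm5345 did not pass with the block.

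Some genes and lists changed sign or, for lists, the direction of the test. With limma-voom, log2 fold changes were -0.045 for Nlrp1b, 0.061 for mt-Nd6, -0.058 for Marco, 0.011 for Fn1 and -0.055 for Reln. With the hepatocyte covariate they were 0.033 for Clec4f and 0.020 for Gata2, and the hepatocyte list, on which it is built, had a median of 0.0013 with the test pointing down. With both doubted libraries left out they were -0.34 for Nlrp1b, -0.28 for Hspa1a, -0.034 for Egr2, 0.23 for Fn1, -0.067 for Sirpa and -0.092 for Reln, and the interferon gamma list had a median of 0.013 with the test pointing down. With 1 library left out the ranges were -0.23 to 0.13 for Fn1, -0.12 to 0.41 for Sirpa, -0.23 to 0.52 for mt-Nd4l, -0.52 to 0.062 for mt-Nd6, -0.43 to 0.023 for Cdh5, -0.50 to 0.032 for Clec4f, -0.37 to 0.041 for Stab2, -0.16 to 0.71 for Alb, -0.58 to 0.044 for Itgb3, -0.45 to 0.059 for Gata2, -0.10 to 0.65 for Sox9, -0.15 to 0.66 for Nlrp1b, -0.025 to 0.37 for Reln and -0.043 to 0.92 for Fgg. List medians ran from 0.018 to 0.38 for NF-kB, with the test pointing down without wild type replicate 1, -0.070 to 0.45 for the interferon gamma response, -0.051 to 0.27 for immediate early genes and -0.11 to 0.59 for hepatocytes. In data simulated at these depths and this spread 8.96% of genes changed 2-fold were called, and what depth alone limits was not separated.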

Other observations

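The tests by other splits of the libraries and of flanking sequence near Msr1 were set before their results were seen. Those of the swapped libraries, mt-Nd3, the genes away from Msr1, substrains, neutrophils, pancreatic genes and windows along the chromosomes were chosen only after the results were seen.

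Transcripts of pancreatic acinar cells, a cell type the labels do not name, appeared in 4 of the 6 libraries. A list of 21 digestive enzyme and related genes summed to 17298, 13954 and 34425 counts in wild type replicates 1, 2 and 3, to 11283 in SRA-/- replicate 2, and to 237 and 76 in SRA-/- replicates 1 and 3. The chymotrypsin gene Ctrb1 reached 5857 counts and the lipase gene Pnlip 5054 in wild type replicate 3, with 15 and 0 in SRA-/- replicate 3. The list was chosen after the values were seen, and 0 of its genes passed edgeR's test between the groups, 1 having an unadjusted p under 0.05, where DESeq2 called 0, limma-voom 1, and edgeR 19 without SRA-/- replicate 2. Pancreatic tissue in 4 preparations is a candidate source, as is carry-over of reads from another library of the run. Log2 ratios between these libraries varied little over the genes (median SD 0.28), which is consistent with either, and an effect of genotype stays untested, since 1 SRA-/- library carried the genes.

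Several called genes separated the groups almost as present or absent. A swapped pair of libraries is argued against by the labelled split, in which 7 genes differed by a gap of at least 3 log2 units, against at most 1 in the other splits of the 10. More mitochondrial RNA in SRA-/- cells is argued against for mt-Nd3 by the other mitochondrially encoded genes. Of these, 0 had a log2 fold change of 1 or more (median -0.078). The same median leaves open a mitochondrial DNA variant that moves reads between mt-Nd3 and the nuclear copy Gm28438. The opposite changes of these 2 genes were seen before the check was set, so it could hardly fail. Pooled CPM went from 57.8 to 1.46 for Gm28438 and from 1.78 to 11.9 for mt-Nd3. The gain of mt-Nd3 was thus smaller than the loss of Gm28438. Reads aligned to several places were not counted, so the 2 changes need not balance and their sizes do not decide the question. Sequence carried with the targeted allele may account for Gm5345 and Gm16348 (Fisher's exact p = 0.00103, resting on these 2 genes). It does not account for the other 8, which lie on other chromosomes. A difference of C57BL/6 substrain between the groups may add to these. Nnt, disrupted by a deletion in C57BL/6J, had a log2 fold change of -1.36 with no overlap. It was named by a rule that asks for no overlap and a small p, so this check could hardly fail. DESeq2 and limma-voom called Nnt, and edgeR's main fit did not (adjusted p 0.438). Nnt did pass edgeR's test with no filter on low counts, without wild type replicate 3 and with the hepatocyte covariate. An effect of the missing receptor stays open for each called gene, and no genotype was read here.

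The neutrophil list was higher in SRA-/- cells by camera with the preset correlation (adjusted p = 0.611 with an estimated correlation), and SRA-/- replicate 2, at -0.37, lay below wild type replicate 3, at -0.11. A lower share of hepatocyte RNA as the whole cause is argued against by the hepatocyte list itself. It took 11.8%, 9.60% and 5.06% of the counts in wild type replicates 1, 2 and 3. In SRA-/- replicates 1, 2 and 3 it took 8.79%, 8.24% and 13.9%, so the groups overlapped and the highest share was in an SRA-/- library. The neutrophil minus sinusoidal endothelial median was also higher in every SRA-/- library, by a gap of 0.32 log2 units. That gap came through the high endothelial value of wild type replicate 3 (0.53), so it rests on 1 library and adds little. Blood carried into the preparations stays open: the neutrophil minus platelet median separated the groups by 0.80, partly through the low platelet value of SRA-/- replicate 2 (-0.56), but erythroid genes were higher in SRA-/- cells and the neutrophil minus erythroid median overlapped, at -0.82 in SRA-/- replicate 2 and 0.27 in wild type replicate 3. More neutrophils in the SRA-/- livers may be a hypothesis to test, as may more transcript per neutrophil, and bulk RNA does not separate them.

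Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The labelled split gave 10 changed genes by edgeR, 7 higher and 3 lower, and 2 near Msr1, where the highest of the other splits gave 0 for each, so that 1 split gave as many. At an unadjusted p under 0.05 it gave 661 genes, where 6 of the other splits gave more, up to 2684. It gave 18 lists, where the highest of the other splits gave 23 and 4 of the 10 splits, the labelled one included, gave 18 or more.

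Genes with an unadjusted p under 0.005 were counted in 276 windows of 10 Mb. They were most concentrated on chromosome 3 between 90 and 100 Mb, with 10 of 180 tested genes (hypergeometric test across genes, adjusted p 2.82e-05). Among these were Ctsk, the nearby genes Gm42743 and Fcgr1, and the nearby genes S100a6, S100a8 and S100a9 (90520189 to 90603028). S100a8 and S100a9 are in the neutrophil list, so this window is not independent of that list. On the Y chromosome between 90 and 100 Mb there were 3 of 3. On chromosome 8, the window from 40 to 50 Mb, which holds Msr1, had 3 of 64 (adjusted p 0.361 by the same test). Next to it, the window from 30 to 40 Mb had 3 of 37 (adjusted p 0.0946 by the same test). The window from 160 to 170 Mb on the X chromosome had the same values, so the one on chromosome 8 did not stand out. The hypergeometric test takes genes as independent, and among the other splits of the libraries 1 window held up to 7 such genes.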
